A study of Mus musculus with 7 samples.

How the data were processed

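Total RNA from the livers of 7 male C57BL/6J mice, a common inbred laboratory strain, was hybridised to Illumina mouse BeadArrays, 1 array per sample. All animals were 28 days old. Per the labels, 4 samples were controls and 3 came from offspring exposed to ethanol in utero, where the dam drank 10% ethanol (v/v) freely from fertilization to gestational day 8.5. The treatment label was the same on control and ethanol samples, so each sample's group was taken from its title. Per the labels' protocols, RNA was extracted with a QIAGEN RNeasy-Plus kit, had an RNA integrity number of at least 9, and was turned into biotinylated cRNA with the Illumina TotalPrep kit. The labels call the samples replicates without saying whether each came from its own litter, so p-values measure the spread between these 7 samples, and littermates in 1 group would make them too small.

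The values used were the authors' deposited intensities, on a linear scale, for 45281 probes. The submitters' processing notes name GenomeStudio. Its version, and the background correction and normalization chosen in it, were not given in the sources used here. From the deposited intensities themselves, values went below 0 (down to between -30.3 and -22.8 per array), so a background had been subtracted. The medians of the 7 arrays lay between 5.13 and 5.94 and the upper quartiles between 50.1 and 51.7, so the arrays had been scaled to each other, while the maxima ran from 50423 to 63235. A second deposited table with signals and detection p-values was not used, because the names of its 14 columns matched no label of a sample. During a first look at the files its signals were correlated with the values used here, before it was set aside, and no result rests on that. The detection p-values that the first plan relied on were therefore not used, and the alternative fixed in the same plan became the main analysis.

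That analysis corrected the intensities with the normexp method at an offset of 50 in limma, took log2 and applied quantile normalization between arrays. Since the deposited intensities had already been background-subtracted, the normexp step here mainly made low values positive. A log2 fold change on this offset scale understates the change of dim probes, and the unlogged intensities of both groups are given for the genes described in most detail. A probe was tested where its normalized value was above the array median on at least 3 arrays, which left 23829 probes. A probe was called above background on an array where its deposited intensity exceeded 3 times the noise SD of that array, with the noise taken as the root mean square of the negative values. By this measure between 13951 and 15068 probes per array were above background, with limits between 21.3 and 26.9 intensity units. Of the tested probes, 14703 were above background on at least 3 arrays. The number of arrays limits the precision of every value.

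Probes were named from the platform annotation, with symbols brought up to date through the Entrez gene ID in an NCBI RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names only. Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. Of those with 1 symbol, 34807 were matched through the ID, and the others kept the annotation's name. No probe with several symbols was named. No coordinates are given because the files name no genome build. The tested probes covered 12769 genes.

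Ethanol samples were compared with control samples by a linear model with moderated variances in limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Each log2 fold change is ethanol minus control and is given with its standard error (SE). A total of 37 gene lists, covering growth, metabolism, stress, sex bias, zonation and the cell types a liver sample can hold, was written before the data were examined, as were the model, the thresholds and most alternatives. Each list was tested with camera at a preset correlation of 0.01 between genes, on the brightest tested probe of each gene, and again with the correlation estimated from the data and with fry. With 7 samples the estimated correlation is itself uncertain. The mean log2 level of each list per animal was compared between groups by an exact permutation test over the 35 splits of 7 animals into 4 and 3, two-sided, where the smallest p is 0.0286. All list p-values were adjusted over the 37 lists. Genes counted as adjusted over the list alone had their limma p-values adjusted among the tested members of that list. Lists share genes, so their results are not independent.

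The genes to be named were fixed by a rule before the data were examined. Every gene past the threshold was named, then the tested genes with the smallest unadjusted p until 20 were named, given as values that did not pass. The 4 members with the largest moderated statistic were added for each list that passed camera and for the 6 lists on growth hormone and IGF signalling, imprinted growth genes, alcohol and aldehyde metabolism, methionine, folate and DNA methylation, and male-biased and female-biased liver genes. Igf1, Igf2, H19, Afp, Adh1, Aldh2 and Cyp2e1 were added where tested. H19 was not among the tested genes.

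The procedure was tested on simulated intensities with the noise of these arrays, in which 22655 probes passed the filter. Of 50 probes simulated at each size for this comparison, 4 were called at a log2 change of 0.5, 37 at 1, 46 at 2 and 50 at 4, and 9 unchanged probes were called. The changed probes were drawn only from tested probes whose mean intensity was above the background limits, so these shares do not hold for dimmer tested probes. Noise was drawn independently for each probe and array. The false calls therefore do not cover variation that many probes of 1 animal share. A simulated list of 20 genes shifted by 0.5 had a fitted median of 0.38, the understatement that the offset brings. Alternatives covered the background correction, its offset, the normalization, the filter on dim probes, the replicate number as a block, the variance model, array weights, the choice of probe per gene, the set test and leaving out each sample in turn. Array position, chip or scan date were not analysed here, so no technical batch could be tested. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with matplotlib 3.10.9 were used.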

Results

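Liver transcript levels were measured on 7 arrays, 4 from control male mice and 3 from male mice of the same strain and age whose dams had drunk 10% ethanol in early pregnancy. The series describes the exposure as a mouse model of fetal alcohol syndrome with restricted growth after birth. The comparison asks which genes differ in the liver at postnatal day 28, after an exposure that ended at gestational day 8.5. Over the tested probes, the correlation of log2 levels ranged from 0.987 to 0.995 between control animals, from 0.988 to 0.990 between ethanol animals and from 0.981 to 0.992 across groups. These correlations are across probes, which are not independent replicates.

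A total of 4 genes passed the threshold. Cyp4a12a, a male-biased fatty acid hydroxylase of the cytochrome P450 family, rose from an intensity of 52.8 ± 46.3 (SD, n = 4) in control livers to 3911 ± 3392 (SD, n = 3) in ethanol livers, a log2 fold change of 4.58 ± 0.58 (SE). In control livers it was above background in 3 of 4 animals. Tmem254a, which encodes a small transmembrane protein, rose from 2618 ± 221 to 4938 ± 482, a log2 fold change of 0.88 ± 0.10. Angptl8, a hormone-like protein made after feeding that restrains lipoprotein lipase, fell from 3370 ± 704 to 938 ± 364, a log2 fold change of -1.81 ± 0.21. Sult2a1, a female-biased sulfotransferase of steroids and bile acids, fell from 131 ± 48.2 to 5.45 ± 11.9 and was not above background in any ethanol animal. Its log2 fold change was -1.39 ± 0.18. Set against the lowest signal above background on the ethanol arrays, on the normalized scale, the control level was at least 2.05-fold higher.

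Each of these genes had an adjusted p of 0.0394 in limma, and in each the 3 ethanol values lay outside the range of the 4 control values. A probe without a gene name here, ILMN_2481836, also fell, from 112 ± 6.98 to 44.0 ± 7.28 (log2 fold change -0.67 ± 0.08, adjusted p 0.0394). Among 23829 tested probes, 5 passed, 2 higher and 3 lower in ethanol livers. At an unadjusted p under 0.05 there were 2096 probes, 982 higher and 1114 lower, where chance alone gives about 1191 on average. This unadjusted count was not compared with other groupings of the animals, so the excess is not read as signal. The count of 5 depended on single animals. It was 0 without control 1, control 3 or control 4, 1 without control 2, 2 without ethanol 2, 6 without ethanol 3 and 27 without ethanol 1. The log2 fold changes moved less in these runs, from 3.85 to 5.45 for Cyp4a12a, 0.82 to 0.95 for Tmem254a, -2.07 to -1.62 for Angptl8, -1.50 to -1.25 for Sult2a1 and -0.71 to -0.62 for ILMN_2481836. The count was also 0 when only probes above background on at least 3 arrays were tested or when variances were not moderated. Without background correction 11 probes passed, none of them among these 5. Of 16 other settings, runs without 1 animal included, Cyp4a12a and Angptl8 passed in 8 each, Sult2a1 and Tmem254a in 6 each and ILMN_2481836 in 5. The adjusted p of Cyp4a12a in limma was 0.334 without background correction and 0.409 with trended robust variances.

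The genes next in order of p did not pass, and their values are given for the record. Socs2, a feedback inhibitor of growth hormone signalling, had an intensity of 3048 ± 660 in control and 1074 ± 362 in ethanol livers, a log2 fold change of -1.48 ± 0.21 with an adjusted p of 0.0864. Pigr, the receptor that carries polymeric immunoglobulin into bile, had a log2 fold change of 0.59 ± 0.09 and an adjusted p of 0.0864. Cyp4a12b, a near-identical neighbour in sequence of Cyp4a12a, had 22.4 ± 22.4 in control livers, where 1 of 4 animals was above background, and 1205 ± 1177 in ethanol livers (log2 fold change 3.36 ± 0.51, adjusted p 0.110). The other values higher in ethanol livers were those of Egfr, the epidermal growth factor receptor (1.04 on the log2 scale), Cdhr5, a brush border cadherin (0.81), Ly6e, a lipid-anchored surface protein (0.75, and 0.75 at its second probe), Arsa, the lysosomal arylsulfatase A (0.67), Rrm2, a ribonucleotide reductase subunit (0.66), and Prpf4, a splicing factor (0.59, with an intensity of 27.5 ± 4.35 in control and 76.3 ± 3.64 in ethanol livers). The other probes of Prpf4 gave 0.07 and 0.06, that of Arsa -0.19, that of Rrm2 0.23 and those of Egfr 0.19 to 1.00. Lower values were those of Cyp17a1, a steroid hydroxylase (-1.14), Vldlr, the very low density lipoprotein receptor (-0.90), Hamp2, a paralog of the iron hormone hepcidin (-0.88), Slco1a4, an organic anion transporter (-0.69), Lima1, an actin-binding protein (-0.66), Cables1, an adaptor of cyclin-dependent kinases (-0.64), and Pparg, a nuclear receptor of lipid storage (-0.48). The other probes of Vldlr gave -0.59 and -0.62, that of Lima1 -0.22 and that of Pparg -0.08. Adjusted p-values of these genes ran up to 0.184. Some passed in other settings. Without a filter on dim probes Prpf4 (adjusted p 0.0342), Pigr (0.0433) and Socs2 (0.0433) did, and with the values as given Cyp4a12b (0.0335). Without ethanol 1 it was Pigr (0.0478), Cyp4a12b (0.00340) and Vldlr (0.0443), without ethanol 3 Cyp4a12b (0.0474) and without control 2 Hamp2 (0.0404).

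**Figure D1:**
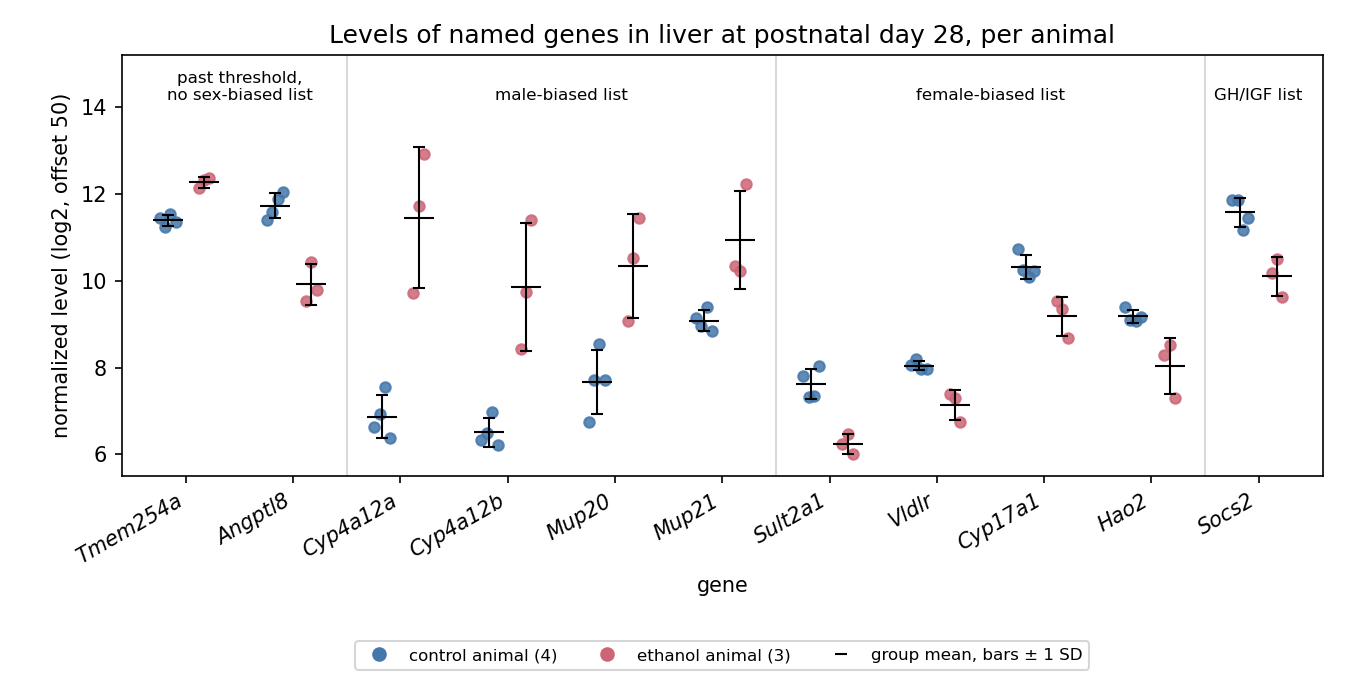
Normalized log2 levels (vertical axis, offset 50) of 11 named genes (horizontal axis) in each animal, with 4 control animals in blue, 3 ethanol animals in red, and group means with bars of 1 SD. In each gene drawn the ethanol values lie outside the control range; Cyp4a12a, Tmem254a, Angptl8 and Sult2a1 passed the threshold, and the ethanol animals spread widely for Cyp4a12a (SD 1.62 against 0.50 in controls).

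Genes that adult male livers express more than female livers had a higher median in the exposed males, and genes with the opposite bias a lower one. Both calls passed camera with the preset correlation (adjusted p 2.44e-15 and 4.26e-08) but not with an estimated correlation (adjusted p = 0.457 for each). Both sets are largely set by the sex-specific pattern of growth hormone secretion. Of 23 male-biased genes tested, 22 were higher and 1 lower in ethanol livers, with a median log2 fold change of 0.65. Runs without 1 animal gave medians from 0.40 (without ethanol 3) to 0.89 (without ethanol 1). Of the 23 genes, 1 passed over all tested probes (Cyp4a12a), and 14 passed, all higher, when adjusted over the list alone. Besides the Cyp4a12 genes, Mup20, a urinary pheromone protein, had an intensity of 156 ± 112 in control and 1524 ± 1113 in ethanol livers (log2 fold change 2.67 ± 0.50), and Mup21, of the same family, 481 ± 96.4 and 2360 ± 2038 (1.85 ± 0.39). Their adjusted p over all probes was 0.233 and 0.293. Mup21 had 1.20 without ethanol 3, where it passed (adjusted p 0.0474), and Mup20 passed without ethanol 1 (3.31, 0.0254). Hsd3b5, a male-specific steroid reductase chosen for mention after its values were seen, had 2.74 ± 0.63.

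Of 23 female-biased genes tested, 18 were lower and 5 higher, with a median of -0.48. The size of this median was unsteady, at -0.24 without ethanol 3, -0.76 without ethanol 2, -0.13 without a filter on dim probes and -0.80 with probes above background only. Of the 23 genes, 1 passed over all probes (Sult2a1). Adjusted over the list alone, 10 passed as lower, and 1, the transporter gene Slc22a30, as higher (0.64 ± 0.18). Cyp17a1 fell from 1223 ± 246 to 532 ± 176, Vldlr from 194 ± 20.6 to 73.3 ± 31.6, and Hao2, a peroxisomal oxidase of hydroxy acids, from 513 ± 54.3 to 208 ± 109 (log2 fold change -1.15 ± 0.23). Each passed when adjusted over the list alone and not over all probes. The largest fitted falls, named after they were seen, were those of Sult2a2 (-3.79 ± 1.00) and Cyp2b13 (-2.81 ± 0.58).

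With an estimated correlation the unadjusted p was 0.0228 for the male-biased list and 0.0322 for the female-biased list, and fry gave an adjusted p of 0.408 for each, so neither call held there. The mean log2 level of the male-biased list per animal, relative to the control mean, was 0.58, 1.03 and 1.56 in the 3 ethanol animals against an SD of 0.26 between controls. That of the female-biased list was -0.41, -0.47 and -1.32 against an SD of 0.05. In both lists the groups did not overlap (exact permutation p 0.0286, the smallest that 35 splits can give, 0.529 after adjustment over the 37 lists). In the male-biased list 10 genes had no overlap between groups, all higher, and in the female-biased list 10, all lower, where chance gives 5.71% of genes in both directions together. That share is an average over splits, and the share over all tested genes was not counted. Other lists lay on both sides of it, such as 0 of 23 pericentral genes, and 3 higher and 11 lower of 54 oxidative phosphorylation genes. Of the 20 genes with the smallest p, 5 belonged to these lists, where 0.0720 were expected from the 46 listed genes among the 12769 tested (Fisher's exact test, one-sided, p 7.22e-09, which treats genes as independent). This test was not among those planned and was run for these lists only, on the same contrast. Its units are genes and not animals, so it does not measure the spread between animals and is no separate support. Near-identical family members (Cyp4a12a and Cyp4a12b, the Mup genes, Sult2a1 and Sult2a2, Cyp2b9 and Cyp2b13) can share hybridisation signal, so they are not independent readings. Kupffer cell and macrophage markers also differed between animals, at 0.30 and 0.50 in ethanol 1 and 2 and -0.17 in ethanol 3, the animal with the largest shift in both sex-biased lists.

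**Figure D2:**
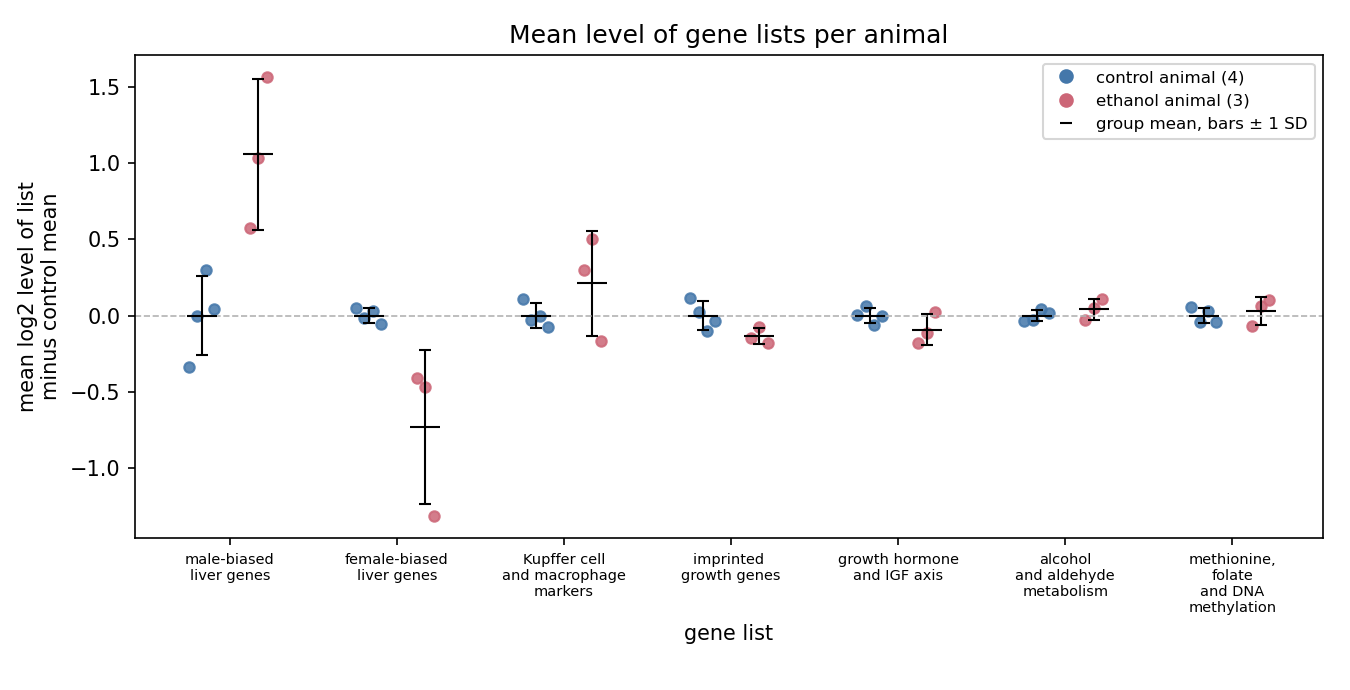
Mean log2 level of 7 gene lists (horizontal axis) in each animal relative to the control mean (vertical axis, log2 units), with 4 control animals in blue, 3 ethanol animals in red, and group means with bars of 1 SD. The ethanol animals lie above all controls for the male-biased list (0.58 to 1.56) and below all controls for the female-biased list (-0.41 to -1.32).

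Genes of the growth hormone and IGF axis had no shift past the test. Over 18 tested genes the median log2 fold change was -0.01 and camera's adjusted p 0.938, with the per-gene mean at -0.09. Only Socs2 passed when adjusted over the list alone. Igf1, the main growth factor secreted by the liver, had 9662 ± 915 in control and 11342 ± 1468 in ethanol livers (0.19 ± 0.10, adjusted p 0.638). Igfals, its carrier subunit, had 0.41 ± 0.12, Igfbp2, a binding protein, -0.47 ± 0.18 (second probe -0.28), and the fetal growth factor Igf2 -0.58 ± 0.25 (123 ± 79.7 and 51.2 ± 8.31). Without control 4 Igfbp2 had -0.29, without control 1 Igf2 had -0.33, and without ethanol 2 Igf1 had 0.12. None of these passed.

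Imprinted growth genes had a median of -0.02 over 18 genes, 9 higher and 9 lower (camera's adjusted p 0.204). Adjusted over the list alone, 3 members passed. Grb10, an inhibitor of insulin and IGF receptor signalling, fell from 312 ± 32.0 to 193 ± 34.2 (-0.54 ± 0.11, second probe -0.02), and Peg3, a paternally expressed zinc finger gene, fell from 120 ± 40.7 to 47.3 ± 19.6 (-0.68 ± 0.17). Gnas, which encodes a stimulatory G protein subunit, rose by that measure (0.35 ± 0.10), while its other probes gave values from -0.46 to 0.34. Over all probes none of the 3 passed. Cdkn1c, a cell cycle inhibitor, had -0.60 ± 0.21, and -0.31 without ethanol 3. Afp, the fetal counterpart of albumin, was not above background in any animal (9.75 ± 7.03 and 4.52 ± 3.57).

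Genes that clear alcohol showed no shift past the test. The list of alcohol and aldehyde metabolism had a median of 0.05 over 24 genes (adjusted p 0.745), and none passed, also when adjusted over the list alone. Adh1, the main liver alcohol dehydrogenase, had 39567 ± 4405 and 44493 ± 3791, Aldh2, the mitochondrial acetaldehyde dehydrogenase, 29667 ± 4385 and 32165 ± 575, and Cyp2e1, an ethanol-inducible P450, 43422 ± 7716 and 47367 ± 2526. Each of these log2 fold changes was 0.05, with SEs of 0.10, 0.10 and 0.13 and adjusted p-values of 0.926 to 0.948. Adh1 and Cyp2e1 lay close to the highest intensities of the arrays (maxima from 50423 to 63235), so a difference there may be understated, which was not tested. The list members with the largest moderated statistics were Aox3 (0.46), Adh4 (0.35), Adh7 (-0.31) and Adh5 (0.27, other probes 0.02 and 0.09). Without ethanol 3 Aox3 had 0.21 and Adh7 -0.14, and without control 1 Adh4 had 0.21. Methionine, folate and DNA methylation genes had a median of 0.00 over 30 genes, 15 higher and 15 lower (adjusted p 0.745), and none passed there either. Its leading members were Mthfd2, a mitochondrial folate enzyme (0.56, second probe 0.25), Folr2, a folate receptor of macrophages (0.45), Mat2b, a regulatory subunit of methionine adenosyltransferase (-0.31, other probes -0.09 and 0.23), and Slc46a1, a folate transporter (0.28, and 0.17 without ethanol 3). The medians of the growth hormone, imprinted, alcohol and methionine lists changed sign in some runs without 1 animal, within -0.10 to 0.07.

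In all, 8 of the 37 lists passed camera with the preset correlation, 3 up and 5 down, and 0 passed with an estimated correlation or with fry (3 at an unadjusted p under 0.05 in each). Besides the sex-biased lists, 6 lists passed with small shifts and without any member past the threshold, also adjusted over the list alone. Ribosomal protein genes fell by a median of 0.10 over 49 genes (adjusted p 9.85e-04, and adjusted p = 0.868 with an estimated correlation), with Rpl3 at -0.21, Rps26 at -0.18, Rpl35 at -0.24 and Rpl9 at -0.25 (-0.16 without ethanol 3). Oxidative phosphorylation genes fell by a median of 0.08 over 54 genes (adjusted p 0.0254, and 0.868 with an estimated correlation), with Ndufb9 of complex I at -0.29, Cox7b and Cox4i1 of complex IV at -0.27 and -0.24, and Sdhd of complex II at -0.25. Immediate early genes, which respond within minutes to stimuli, fell by 0.16 over 21 genes (adjusted p 0.0167, and 0.457 with an estimated correlation), with Ier3 at -0.33 and Dusp6 at -0.42 (-0.21 without ethanol 3). Gadd45b was above background in 4 control animals and in 0 ethanol animals, at least 1.21-fold higher in controls, and Atf3 was not above background in any animal.

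Kupffer cell and macrophage markers rose by a median of 0.20 over 23 genes (adjusted p 0.00146, and 0.868 with an estimated correlation), with the complement genes C1qb (0.43) and C1qc (0.43), Folr2 (0.45) and Cd74, the invariant chain of antigen presentation (0.71). The value of Cd74 rested on ethanol 2 and was 0.27 without it, and its other probes gave 0.47 and 0.56. Interferon response genes rose by 0.10 over 29 genes (adjusted p 0.0293, and 0.868 with an estimated correlation), with the antigen processing genes Psmb8 (0.53, second probe 0.05) and Tap1 (0.28), Dhx58 (0.30) and Oas1g (0.19). Without ethanol 2 Psmb8 had 0.29 and Tap1 0.17, and without ethanol 3 Dhx58 had 0.17. Stellate cell and fibroblast markers fell by 0.13 over 27 genes (adjusted p 0.0293, and 0.868 with an estimated correlation), with Col3a1 at -0.29 (second probe 0.10) and Colec10 at -0.28, while Gas6 had 0.36 (0.24 without ethanol 1) and Bgn 0.28. Leaving out 1 animal ended each of these 6 calls. The ribosomal call was lost without ethanol 3 (median -0.07, adjusted p 0.0693) and the macrophage call without ethanol 2 (0.03, 0.441). Over all runs without 1 animal the macrophage median ranged from 0.03 to 0.46. The immediate early call was lost without ethanol 2 (-0.11, 0.0920) or ethanol 3 (-0.18, 0.0807), and the interferon call without control 4 (0.07, 0.253) or ethanol 2 (0.05, 0.513). That of oxidative phosphorylation was lost without control 3 (-0.08, 0.0982), control 4 (-0.05, 0.180) or ethanol 1 (-0.05, 0.245). That of stellate cells was lost without control 1 (-0.09, 0.0505), control 2 (-0.11, 0.335), ethanol 1 (-0.09, 0.0681) or ethanol 2 (-0.08, 0.0920). Processing also ended 5 of these calls. That of oxidative phosphorylation was lost without background correction (adjusted p 0.0785), with an offset of 16 (0.0555), median centring (0.0865), the values as given (0.279) or probes above background only (0.0628). The interferon call was lost without background correction (0.0836) or with median centring (0.0544), and the stellate call without background correction (0.0601) or with probes above background only (0.0571). The ribosomal call was lost with the values as given (0.147) and the immediate early call with probes above background only (0.0856).

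**Figure D3:**
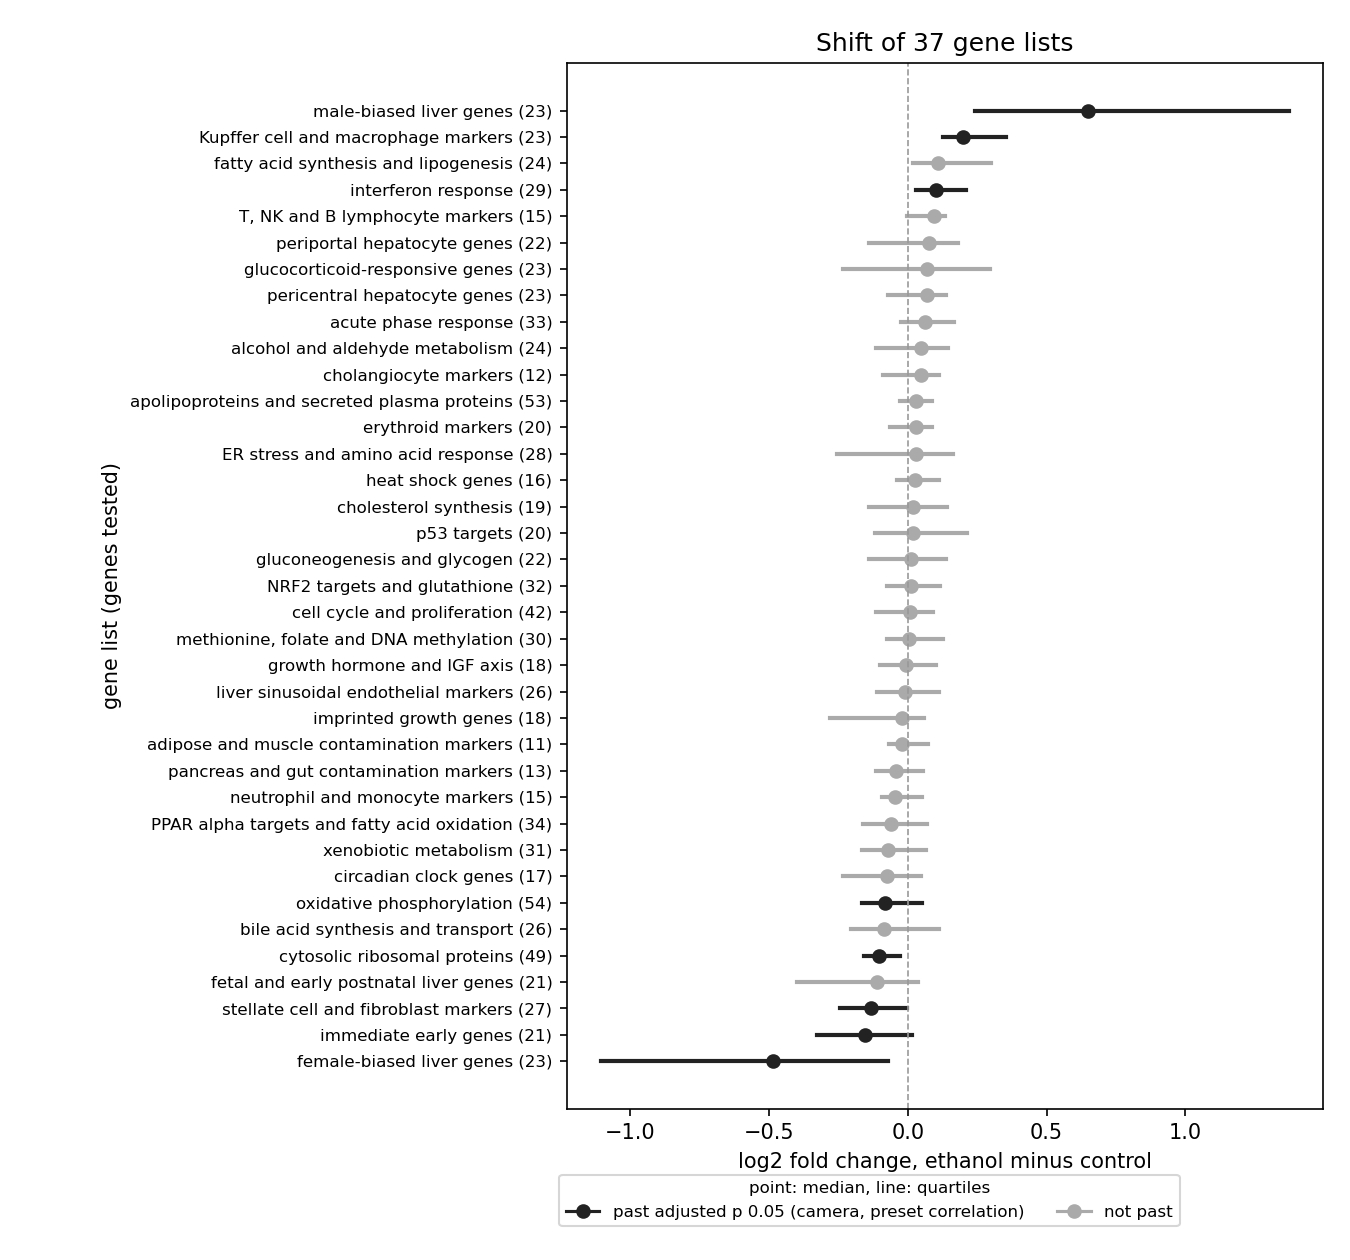
Median log2 fold change, ethanol minus control (horizontal axis), of each of 37 gene lists (vertical axis, with the number of genes tested), with lines from the lower to the upper quartile of the genes and in black the 8 lists past an adjusted p of 0.05 in camera with the preset correlation. The male-biased list (0.65) and the female-biased list (-0.48) lie farthest from 0.

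The other 29 lists did not pass. Among markers of other cell types, medians were 0.09 for lymphocytes, -0.04 for neutrophils and monocytes, 0.03 for erythroid cells, -0.01 for sinusoidal endothelium and 0.05 for cholangiocytes. Markers of pancreas and gut had -0.04 and those of fat and muscle -0.02. Pericentral and periportal hepatocyte genes had 0.07 and 0.08. Fetal and early postnatal liver genes had -0.11 (adjusted p 0.0823), lipogenic genes 0.11 (0.0823), bile acid genes -0.08 (0.0823) and PPAR alpha targets with fatty acid oxidation -0.06 (0.0911). Cholesterol synthesis had 0.02, gluconeogenesis and glycogen 0.01, and cell cycle genes 0.01. The mean over genes had the opposite sign to the median for ER stress (median 0.03, mean -0.06), NRF2 targets (0.01 and -0.01), gluconeogenesis, neutrophils and monocytes, pancreas and gut, and fat and muscle, as did camera's direction for ER stress, cholesterol synthesis, gluconeogenesis, sinusoidal endothelium, and fat and muscle, all with adjusted p-values of at least 0.738.

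The spread between exposed animals was not distinguishable from that between controls. The median within-group variance of log2 levels was 0.0149 in ethanol and 0.0147 in control animals, a ratio of 1.02 (exact permutation test, two-sided, p 0.943). The other splits of the 7 animals gave ratios from 0.667 to 1.21. This test is centred on a ratio of 1, while the median over all 35 splits was 0.905. A median of variances from 3 animals lies below one from 4 by construction, so the p of 0.943 is no measure of equality. A ratio at least as high as the real one came in 9 of the 35 splits, the real one included. Without ethanol 1, 2 or 3 the ratio was 0.672, 0.671 and 0.708. Medians of variances from 2 animals lie lower still by construction.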

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

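A total of 104 sets of 4 control values was searched for an animal far from the other 3, and 5 were found, where chance gives about 5.2, so no pattern is read from them. Control 1 stood apart in 3 genes. Its log2 level of Pparg was 8.62, where the other controls lay between 8.44 and 8.46. Its level of Folr2 was 7.99, against 8.42 to 8.45, and that of Adh4 was 10.9, against 11.5 to 11.6. Control 2 had an Oas1g level of 8.26, against 8.01 to 8.05. For the list of p53 targets, the mean log2 level of control 4 relative to the control mean was -0.12, against 0.03 to 0.05 in the other controls.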

How the results depend on the processing

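The offset of 16 and the filter on probes above background were chosen after seeing the data. Direction held in all these settings for the 5 probes past the threshold and for both sex-biased lists. The number of probes past the threshold (5) was 11 without background correction, 3 with an offset of 16, 8 without a filter on dim probes, 0 with probes above background only, 1 with trended robust variances, 0 with unmoderated variances (1847 at an unadjusted p under 0.05, 1495 with probes above background only), 8 at an adjusted p under 0.1 and 2096 at an unadjusted p under 0.05. Leaving out 1 animal gave 0 to 27. Of these sets, 0 of the 11 and 3 of the 3 were among the main 5. Of the 11 probes 6 were higher, and of the main 5, 2. The replicate number as a block gave 24 probes, 3 of them among the main 5. Same-numbered animals deviated together at r of -0.19, 0.09 and 0.20, and only ethanol 3 correlated best with its own number. These 3 values show no clear pairing by number but cannot exclude it. The block left the 2 sex-biased calls in place and ended those of the oxidative phosphorylation and interferon lists (adjusted p 0.191 each), Tmem254a (0.0810) and ILMN_2481836 (0.117), while Socs2 (0.00501), Mup20 (0.00125), Cyp17a1 (0.0330) and Cyp4a12b (0.0419) passed. Control 4 has no ethanol animal of its number, so the block also takes it out of the comparison. The run without control 4 gave equal log2 fold changes for these genes and lists and lost those 4 calls too, so the losses cannot be put down to the block. None of the 4 gains came in that run. Socs2, Mup20 and Cyp4a12b also passed in other settings without the block, and Cyp17a1 did not. The number of gene lists (8) was 5 without background correction, 5 with probes above background only, and 0 with an estimated correlation or fry, which do not enter the medians (0.65 and -0.48 for the male-biased and female-biased lists). The spread ratio ranged from 0.671 to 1.22 over runs without 1 animal.

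Some medians near 0 changed sign, none past the threshold. That of the growth hormone list was 8.84e-04 with median centring, 5.86e-04 with the values as given, 0.0139 with the replicate block and 0.0179 with probes averaged per gene. That of the methionine list was -7.19e-04 with median centring and -0.0140 with probes above background only, and that of the imprinted list 0.00173 without a filter. Without 1 animal these lists ranged from -0.0460 to 0.0676 (growth hormone), -0.0969 to 0.0348 (imprinted), -0.00419 to 0.0631 (alcohol) and -0.0379 to 0.0690 (methionine), and the log2 fold changes of Aldh2 and Cyp2e1 from -0.0175 to 0.107 and from -0.0785 to 0.119. Apart from filters that change which probes are tested, the cause was not tested. Between 30.8% and 33.3% of probes were above background per array, so changes in dim genes are understated or missed. Filters on detection p, the planned change of the offset that needs detection p, and the chip as a block were not run.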

Other observations

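Lists that did not pass as a whole held members that passed when adjusted over the list alone. These members were chosen after their values were seen, and none passed over all tested probes. In the acute phase list (33 genes, median 0.06, camera's adjusted p 0.619), Orm1 and Orm2, which encode orosomucoids, and Lrg1 had log2 fold changes of 0.61, 0.62 and 0.66, while Hamp, which encodes the iron hormone hepcidin, and its paralog Hamp2 had -1.49 and -0.88. Among plasma proteins (53 genes, median 0.03), the terminal complement genes C8a, C8b and C9 had 0.55, 0.56 and 0.89, and the hormone-binding globulins Serpina6 and Serpina7 had -0.65 and -1.09. In the list of ER stress and amino acid response genes (28 genes, median 0.03, per-gene mean -0.06), Vldlr, the chaperone Hspa5, Trib3 and the fasting hormone Fgf21 had -0.90, -0.37, -0.77 and -0.83, and Ddit4 had 0.65. Other such members were Slco1a4 (-0.69) and Klb (-0.33) for bile acids, Hadhb (-0.32) and Ehhadh (-0.46) for PPAR alpha, Ugt1a9 (0.71), Sult1d1 (-0.65) and Cyp2b13 (-2.81) for xenobiotic metabolism, and Pigr (0.59), Mup20 (2.67) and Hamp for periportal genes. Single members were Pparg for lipogenesis (-0.48), Gstp1 for NRF2 targets (0.70), Rrm2 for the cell cycle (0.66) and Nr1d2 for the clock (-0.53).

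Several genes of the circadian clock spread widely between ethanol animals. Dbp, a transcription factor with a strong daily rhythm, had an intensity of 2308 to 3910 in the 4 control animals, and 4644, 937 and 277 in ethanol 1, 2 and 3. The list had a median of -0.08 over 17 genes (camera's adjusted p 0.214), and the SD of Dbp on the log2 scale was 1.89 between ethanol animals and 0.32 between controls. Ethanol animals 2 and 3 also had the highest levels of Arntl, a core clock gene that peaks at the opposite time of day. Nr1d2, a repressor in the clock, was lower in each ethanol animal than in any control (unadjusted p 0.00135, adjusted 0.336), and Bhlhe40, another repressor, had -0.78 (unadjusted p 0.0142, adjusted 0.472). Sampling times were not analysed here, and no explanation of these values was tested.

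Of the tests below, those of the clock as a covariate, the share of hepatocytes, maturation and the splits for the number of probes were chosen after the result was seen. The higher male-biased and lower female-biased genes in exposed males are the pattern most open to follow-up. Female animals among the controls are argued against by a Y-linked gene above background in 4 of 4 control animals, and a different share of hepatocytes by plasma protein genes, which hepatocytes make. Their median shift was 0.0305 (quartiles -0.03 and 0.09), and 0.04 over the 34 with a mean intensity under 20000 (quartiles -0.02 and 0.13), where the male-biased list had a lower quartile of 0.24 and the female-biased list an upper quartile of -0.07. The male-minus-female score is the mean log2 level of the male-biased list minus that of the female-biased list. With the leading component of the clock genes as a covariate, its group difference was 1.66 ± 0.51 (95% interval 0.25 to 3.06), against 1.79 ± 0.50 without it. The lower bound of 0.25 argues against this component, as a linear term, as the whole cause, but does not settle time of day. The component held 49.9% of the variance of the clock genes. Its scores were 4.33, -3.26 and -3.29 in ethanol 1, 2 and 3, on both sides of the controls (-1.59 to 2.36), so it could take up little of a group difference. A partial contribution of time of day cannot be told apart with 7 animals either, since the interval also holds much smaller differences. A candidate biological explanation, that exposed livers were further along in postnatal maturation, also stays open. Fetal and early postnatal genes had a median of -0.11, which did not pass and overlapped between groups. That list cannot decide the question. As written, it shares Cyp3a16 and Sult1e1 with the female-biased list, and its member Afp was not above background in any animal. Litter, body weight, feeding and growth hormone secretion were not analysed here. The score of the real grouping was the most extreme of the 35 splits (exact permutation p 0.0286, the smallest these splits can give). It joins the 2 lists with the smallest permutation p of the 37, each 0.529 after adjustment, so its rank is no separate support.

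For the lower ribosomal protein and oxidative phosphorylation genes, a shift of all bright probes left by the normalization was tested against 10000 random lists of the same size and level. The medians of -0.10 and -0.08 lay at percentiles 0.02 and 0.52 of these lists, which argues against such a shift in the quantile-normalized values. Other normalizations were not tested in this way. In camera the ribosomal call was lost with the values as given (adjusted p 0.147). That of oxidative phosphorylation was lost with median centring (0.0865) or the values as given (0.279), so a part of the normalization in these calls stays open. That comparison treats genes as independent, which coregulated genes are not. Other groupings of the animals gave a camera p as small in 7 and 9 of the 35 splits, the real one included, so variation between animals stays open. For the other lists past camera the counts were 13 (macrophages), 12 (interferon), 11 (stellate cells) and 3 (immediate early genes). For each sex-biased list only the real grouping gave a camera p as small. These are the lists with the smallest exact permutation p of the 37, each 0.529 after adjustment, so that count is no separate support. No biological explanation was tested.

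Chance is not excluded for either overall count. Of the 35 splits of the animals into 4 and 3, 2 gave at least 5 probes past the threshold, the real one and that of control 1, control 2 and ethanol 2 against the rest, which also gave 5. For the gene lists, 25 of the 35 splits gave at least 8 lists, and the highest other split gave 15. The preset correlation of camera therefore called lists at random groupings of these animals.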
